A study of Mus musculus with 24 samples.

How the data were processed

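The series holds bulk RNA sequencing of acinar-enriched explants from the pancreas of KC mice, which carry an activated Kras allele switched on by Pdx1-Cre in pancreatic cells. The series' own design note instead speaks of KPC organoids and of stranded libraries, and the labels of the single samples were followed. The explants were embedded in rat tail collagen I and cultured, per the labels' protocols. The labels give 2 genotypes, Fgfr2 wild type and Fgfr2 fl/fl, and 3 days of sampling, days 0, 2 and 5. Each of the 6 groups holds 4 libraries, so there are 24 libraries from 8 animals. The labels give 1 code per animal, and the same animal was sampled on each day. Each library within a day came from its own animal, so the p-values of genotype comparisons within a day measure the spread between animals. The comparisons of days and the tests over all 24 libraries reported first carry no animal term. Their p-values therefore leave aside that the same animals recur across days. Replicates 1 to 4 are wild type and replicates 6 to 9 are fl/fl. Replicates 4 and 9, 1 of each genotype, carry codes that lie apart from those of the other 6 animals, here called a separate range. Their codes are not adjacent to each other, and the labels do not say what the codes stand for. Within the main range all wild-type codes come before the fl/fl codes, so code order and genotype cannot be told apart there. On day 0 the second principal component set them apart from the other 6 animals. On days 2 and 5 replicate 6 lay on the same side of the first component as both. On day 5 replicate 8 lay there too, at 1.18, so on these days replicates 4 and 9 were not set apart alone. The fits reported first carry no term for this code range. Such a term was added in an alternative chosen after seeing the data, though the labels do not call the range a batch.

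RNA was extracted with TRIzol and on-column DNase, and libraries were made with an mRNA HyperPrep kit, per the labels' protocols. FastQC 0.11.9, Trim Galore, STAR 2.7.9a, RSEM 1.3.3, DESeq2 1.44.0 and the genome build GRCm39 are named in the submitters' processing notes, with no role or order given there. The deposited gene table holds RSEM expected counts that were not normalised, per the file headers, for 57132 gene identifiers. A second deposited gene table holds TPM, scaled per library by the authors. All 1371168 values of each table were checked against the per-sample files and were equal. The deposited per-sample transcript files hold expected counts, TPM and the isoform percentage, which is the percent of a gene's abundance given to each transcript by the authors' RSEM run. A deposited table of 16725 protein-coding genes holds a normalised signal: checked against the counts, it equals the expected count without its decimals, divided by 1 factor per library. That table served for gene names, positions and one of the alternatives. Of the other identifiers, 35199 were named from a separate gene-name table and 5208 had no symbol. The reference given with the data was of an older mouse build, so its coordinates were not used. It served only to say which Fgfr2 transcripts hold the alternative IIIb or IIIc exon. Positions printed below are those of the deposited protein-coding table, on GRCm39. RSEM divides reads among near-identical transcripts, so counts of pseudogenes and their parent genes are uncertain. Apart from that note, no file states whether the counting used strand. Totals ran from 8725990 to 13159985 expected counts per library.

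The expected counts were rounded and tested with edgeR 4.0.16 in R 4.3.3 (quasi-likelihood F-test, TMM factors, low-count genes removed by filterByExpr, Benjamini-Hochberg adjustment, threshold 0.05). Comparisons of genotype used the 8 libraries of a day. Comparisons of days used the 12 libraries of a genotype, and the tests of whether a change over days differed by genotype used all 24 libraries. Levels are TMM-normalised CPM (counts scaled to a common library total) within the libraries of the fit, so a gene's CPM differs between fits, and the fit is named where 2 scales meet. SE denotes an approximate standard error, the size of a log2 fold change divided by the square root of its F statistic. It is not reliable where a group lies near 0 counts, as for the pseudogenes. A set of 31 gene lists, with 662 of 669 distinct genes found, was tested with camera at a preset correlation of 0.01 on log2 CPM (prior count 2), with Benjamini-Hochberg adjustment within a comparison, for lists with at least 5 tested members. Camera with an estimated correlation and fry were run beside it with limma 3.58.1. Shares and isoform percentages were compared between genotypes by an exact two-sided permutation test.

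The text names Fgfr2, then up to 10 genes with the largest and 10 with the smallest log2 fold change among genes past the threshold whose groups did not overlap in CPM. Their mean CPM had to reach 10 in the higher group (5 for genotype), and predicted, clone-named and sex-linked genes were left out. It also names up to 4 members of each list with the smallest adjusted p. Where fewer than 5 genes passed, the 10 with the smallest unadjusted p could be named. The lists, tests, named-gene rule and all alternatives but the code range were chosen before the data were examined. The alternatives were RLE factors, no low-count filter, a filter of CPM 1 in 4 libraries, DESeq2 1.42.0, limma on log2(TPM + 1) and log2(TPM + 0.1), protein-coding genes alone, removal of acinar enzymes, a single fit of 24 libraries, an animal term (replicate block), and each animal left out. A term for the code range, the 6 animals of the main range and the share of expected counts for Fgfr2 transcripts were added after seeing the data.

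The same animal number marks the same animal on each day in the labels, so the numbers pair the libraries across days. The deviations of an animal from its group means correlated across genes in all 24 pairs of days, with r from 0.0304 to 0.359 and a median of 0.0900, and 11 pairs lay over 0.1. The animal itself gave the highest r in 20 of the 24 pairs. No pair of libraries of a group agreed within sampling noise (chi-square per degree of freedom at least 5.65). The pipeline was tested on simulated data with 200 changed genes, drawn only from genes with a mean of at least 5 CPM. The quasi-likelihood test recovered 81% of 2-fold and 98% of 4-fold changes among 12365 genes in the day 2 genotype design, with 5.29% of its calls false. It recovered 73% and 99% in the wild-type design of day 2 against day 0. In the design for the difference between genotypes it recovered 44% and 92%. Simulated genes were independent, unlike real ones, and no structure shared between animals was simulated. Recovery among genes of lower level, Fgfr2 among them, was not measured. Figures and shares used Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.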

Results

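Bulk RNA sequencing was made of acinar-enriched pancreatic explants from KC mice on days 0, 2 and 5 of culture in collagen. The animals were labelled Fgfr2 wild type (replicates 1 to 4) or Fgfr2 fl/fl (replicates 6 to 9), which gave 4 libraries in each of 6 groups. Library totals ran from 8725990 to 13159985 expected counts. The design compares the genotype labels on each day, successive days within each label, and the change over days between labels. The series title speaks of the transformation of acinar cells by mutant Kras. Fgfr2 encodes a receptor for fibroblast growth factors. Its exon variants IIIb and IIIc are typical of epithelial and mesenchymal cells.

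Fgfr2 was not lower in the libraries labelled fl/fl, so the gene count did not check the label, and these animals are called the libraries labelled fl/fl throughout. On day 0 the expected counts of Fgfr2 were 10.2, 3, 6 and 4.12 in wild-type replicates 1 to 4 and 27, 4.07, 28.5 and 14.4 in fl/fl replicates 6 to 9. The day 0 level, normalised over all 24 libraries, was 2.32 ± 1.02 CPM in wild type and 8.28 ± 5.08 CPM in fl/fl (SD, n = 4 each; exact permutation p = 0.114). On day 2 it was 0.645 ± 0.215 and 1.21 ± 0.346 CPM (n = 4 each; exact p = 0.0571), and on day 5 it was 2.37 ± 1.14 and 2.29 ± 0.986 CPM (n = 4 each; exact p = 0.971). Summed over a group, 23 to 286 counts lay behind these levels. The edgeR log2 difference was 0.89 on day 2 (SE 0.32, adjusted p = 0.354) and -0.02 on day 5 (SE 0.41, adjusted p = 0.986), and on day 0 the gene was too low to be tested. Leaving out replicate 1, 3, 6 or 9, the term for code range and both TPM tests turned the day 5 sign, giving 0.05 to 0.18. Which Fgfr2 exons are flanked by loxP sites is not given in the sources used here, so the whole-gene count does not check for the loss of single exons.

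Transcripts with the IIIb exon made up 27.3% ± 22.6 of Fgfr2 in wild type and 6.50% ± 7.71 in the libraries labelled fl/fl on day 5 (SD, n = 4 each; exact permutation p = 0.171). The percentages were 47.15, 17.56, 44.49 and 0 in replicates 1 to 4 and 0, 10.84, 15.16 and 0 in replicates 6 to 9. Without replicate 4 the difference was -29.9 points (n = 3 and 4; exact p = 0.0286). On leaving out any other animal it was -24.0 to -14.2 points (exact p from 0.171 to 0.286). Among the 6 animals of the main code range the percentages were 36.4 ± 16.4 and 8.67 ± 7.81, with all wild-type animals above all fl/fl animals (n = 3 each; exact p = 0.1, the smallest that 3 against 3 can give). The other range holds 1 animal per genotype, both at 0. On day 0 the percentages were 0 and 12.4 ± 24.8 (n = 4 each; exact p = 1), and on day 2 they were 9.86 ± 11.95 and 2.49 ± 4.38 (n = 4 each; exact p = 0.429). Transcripts with the IIIc exon reached 3.77% ± 7.55 and 13.9% ± 10.6 on day 5 (n = 4 each; exact p = 0.257).

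Acinar digestive enzymes made up most of the transcripts at the start and little by day 5. Their share of counts was 81.8% ± 1.6 in wild type and 83.0% ± 0.7 in fl/fl on day 0 (SD, n = 4 each; exact permutation p = 0.257). It was 21.6% ± 8.4 and 27.1% ± 4.9 on day 2 (n = 4 each; exact p = 0.343) and 2.85% ± 0.73 and 2.36% ± 1.07 on day 5 (n = 4 each; exact p = 0.429). Among the 6 animals of the main code range the shares were 17.5% ± 2.36 and 26.5% ± 5.77 on day 2 (n = 3 each; exact p = 0.1, the smallest possible). On day 5 that subset turned the sign, with fl/fl 0.114 points higher (n = 3 each; exact p = 1). Leaving out wild-type replicate 4 moved the day 2 difference from 5.48 to 9.59 points.

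**Figure D1:**
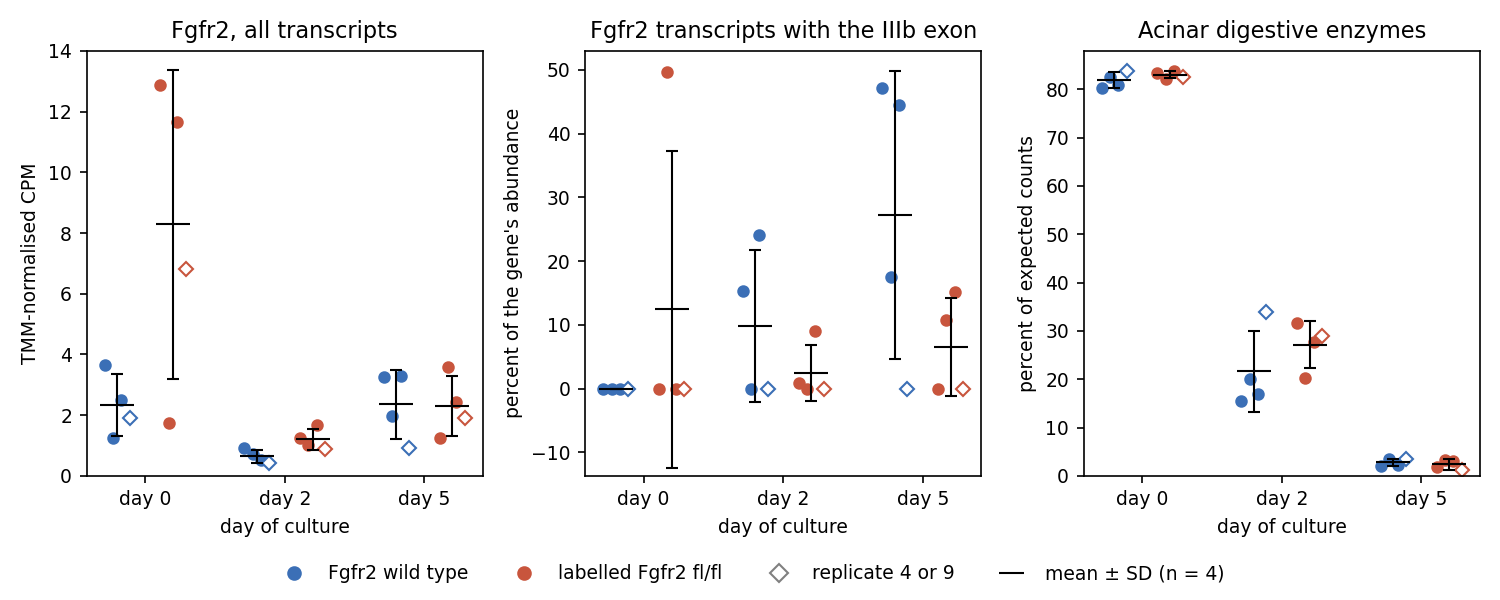
Fgfr2 level (TMM-normalised CPM), percent of Fgfr2 transcripts with the IIIb exon, and percent of expected counts from acinar digestive enzymes, for each of the 24 libraries by day and genotype label; filled circles are animals of the main code range, open diamonds replicates 4 and 9, and black marks the mean ± SD of 4. The acinar share fell from 81.8% and 83.0% on day 0 to 2.85% and 2.36% on day 5, while Fgfr2 levels of the labels overlapped on each day.

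From day 0 to day 2 the wild-type explants lost acinar enzyme transcripts, while single genes such as Lcn2 and Plin2 rose. All 32 tested digestive enzymes fell, with a median log2 change of -5.23. Carboxypeptidase B (Cpb1, chromosome 3, 20302428 to 20329897 on GRCm39) fell from 244017 ± 38325 to 2188 ± 1638 CPM (SD, n = 4 each; log2 -6.80, SE 0.54, edgeR adjusted p = 7.36e-08). Lcn2, an iron-binding acute-phase protein, rose from 24.95 ± 2.50 to 887 ± 364 CPM (log2 5.15, SE 0.35, edgeR adjusted p = 1.21e-08). Plin2, which coats lipid droplets, rose from 5.10 ± 2.28 to 334 ± 70.8 CPM (log2 6.0, SE 0.30, edgeR adjusted p = 7.97e-10).

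In wild type 3910 genes were higher and 3310 lower on day 2 than on day 0, of 13314 tested, and 2202 and 2100 of them changed over 2-fold. The pancreatic serpin Serpini2 fell most among the named genes (log2 -8.89, SE 0.43, edgeR adjusted p = 4.72e-10). Of 22 genes of acinar transcription factors and secretory machinery 1 rose and 19 fell, also when adjusted over the list alone, among them Rbpjl, the acinar subunit of the PTF1 complex (log2 -5.17, SE 0.22, edgeR adjusted p = 1.4e-10). Zg16 of the zymogen granule went from 24254 ± 4019 to 434 ± 194 CPM, and the trefoil factor Tff2 from 2636 ± 438 to 80.3 ± 46.1 CPM. Agr2, which folds secreted mucins, fell by 8.05 on the log2 scale (10 counts against 358 in all; SE 0.46, edgeR adjusted p = 2.34e-09). Of 24 unfolded protein response genes 1 rose and 19 fell, also over the list alone, as did all 20 ribosomal protein genes and 12 of 13 mitochondrially encoded transcripts. Sel1l, part of the degradation machinery of the endoplasmic reticulum, had a log2 change of -3.25 and the proliferation marker Mki67 one of -3.26 (edgeR adjusted p = 1.06e-08 and 0.000774); on log2(TPM + 1) both lay near 0 (-0.06 and -0.02) and did not pass. The camera adjusted p was 2.51e-20 for the enzymes and 8.05e-10 to 1.19e-08 for the ribosomal, mitochondrial and unfolded protein lists. With 1.18e-10 for the transcription factor list, these calls were lost with an estimated correlation (adjusted p = 0.258 with an estimated correlation, and 0.562 for the ribosomal list).

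Members of 2 further lists changed in wild type by day 2, though neither list call held with an estimated correlation. Of 22 NRF2 and glutathione genes 15 rose and 2 fell, with Txnrd1, a thioredoxin reductase, at log2 2.21 (SE 0.20, edgeR adjusted p = 2.97e-07). Of 22 genes of epithelial-mesenchymal transition (EMT) and invasion 10 rose and 1 fell, with Serpine1, an inhibitor of plasminogen activators, at 3.05 (SE 0.26, edgeR adjusted p = 1.43e-07). Both counts were the same when adjusted over the list alone. The camera adjusted p was 0.003 and 0.0204 (adjusted p = 0.736 and 0.779 with an estimated correlation), and the EMT call was also lost without replicate 3 (adjusted p = 0.0772). Tenascin C (Tnc) went from 8 to 5414 counts in all, the tight-junction gene Cldn4 rose by log2 3.96, Ccn1, a target of YAP, by 3.52, Ier3, an early response gene, by 5.17 and the p53 target Phlda3 by 4.19 (edgeR adjusted p at most 1.15e-07 for these 4). Fgfr2 was lower on day 2 (log2 -1.86, SE 0.53, edgeR adjusted p = 0.0076), but higher on log2(TPM + 1), by 0.66 (adjusted p = 0.0499).

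In the libraries labelled fl/fl the change from day 0 to day 2 ran the same way. Again all 32 digestive enzymes fell, with a median of -4.77, and Cpb1 went from 232907 ± 19797 to 2817 ± 965 CPM (SD, n = 4 each; log2 -6.37, SE 0.60, edgeR adjusted p = 4.7e-07). Lcn2 rose from 18.2 ± 5.54 to 612 ± 277 CPM (log2 5.07, SE 0.47, edgeR adjusted p = 3.64e-07) and Plin2 from 4.37 ± 0.918 to 289 ± 50.1 CPM (log2 6.05, SE 0.23, edgeR adjusted p = 5.23e-11). In all, 3852 genes were higher and 3243 lower on day 2, of 13306 tested, and 2111 and 1959 of them changed over 2-fold. Zg16 went from 30526 ± 2738 to 784 ± 119 CPM and Tff2 from 2391 ± 133 to 111 ± 43.3 CPM. Serpini2 fell by 8.42 and Gatm, of creatine synthesis, by 3.83 on the log2 scale (edgeR adjusted p = 8.17e-11 and 7.24e-11). Cldn4 rose by log2 4.11, Ccn1 by 4.17, Serpine1 by 3.46 and Txnrd1 by 2.15 (edgeR adjusted p at most 6.54e-08). Tnc went from 5 to 5677 counts in all and Ier3 from 15 to 11683.

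Of the 22 acinar transcription factor and secretory genes 1 rose and 18 fell in fl/fl, and 19 fell when adjusted over the list alone. All 20 ribosomal protein genes and 12 of 13 mitochondrial transcripts fell, and of 24 unfolded protein response genes 1 rose and 15 fell, with the same counts when adjusted over the list alone. Enzymes and transcription factors had camera adjusted p = 3.84e-20 and 2.27e-09 (adjusted p = 0.0814 for both with an estimated correlation). For the ribosomal, mitochondrial and unfolded protein lists it was 5.49e-11, 9.26e-09 and 1.9e-06 (adjusted p = 0.431, 0.176 and 0.245 with an estimated correlation). Pdia6, a disulfide isomerase, had a log2 change of -2.89 (SE 0.18, edgeR adjusted p = 7.54e-09) that turned to 0.25 on log2(TPM + 1). Of 21 NRF2 and glutathione genes 14 rose and 4 fell (15 and 4 adjusted over the list alone; camera adjusted p = 0.0057, and adjusted p = 0.537 with an estimated correlation). Of 21 EMT and invasion genes 7 rose and 0 fell (6 and 0 adjusted over the list alone; camera adjusted p = 0.0348, and adjusted p = 0.685 with an estimated correlation; adjusted p = 0.0667 without replicate 8). Of 10 genes of antigen presentation 7 rose and 0 fell, also over the list alone, among them the peptide transporter Tap1 at log2 2.61 (SE 0.43, edgeR adjusted p = 0.000112). That list had camera adjusted p = 0.0342 (adjusted p = 0.245 with an estimated correlation; adjusted p = 0.0535 without replicate 7). Fgfr2 was lower on day 2 (log2 -2.77, SE 0.48, edgeR adjusted p = 0.000198), but higher on log2(TPM + 1), by 0.71 (adjusted p = 0.0479).

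These directions are relative to the TMM scale, on which the median gene moved by 0.16 in both labels. TPM is not corrected for the loss of the enzymes, and on log2(TPM + 1) the median gene moved by 2.26 in wild type and 2.16 in fl/fl. On that scale 11568 genes were higher and 151 lower in wild type, and 11551 and 132 in fl/fl. The ribosomal, mitochondrial and unfolded protein medians turned to 1.82, 0.58 and 1.37 in wild type and 1.63, 0.22 and 1.54 in fl/fl on log2(TPM + 1). They still lay below the median of all genes, by -0.44, -1.68 and -0.89 in wild type and -0.53, -1.94 and -0.62 in fl/fl. The enzyme medians stayed negative on log2(TPM + 1) but were smaller in size, at -2.08 in wild type and -1.76 in fl/fl. As raw shares of counts, ribosomal protein transcripts went from 0.357% to 1.26% in wild type, and mitochondrial ones from 0.841% to 1.11%. Without replicate 4 the counts in wild type were 3945 and 3458, and without replicate 9 those in fl/fl were 3692 and 3224. Of 13023 genes tested in both labels 3078 rose in both and 2769 fell in both, where independent calls would give 1148 and 801, and 3 went opposite ways. The log2 changes correlated across genes (r = 0.797), and genes are not independent replicates.

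**Figure D2:**
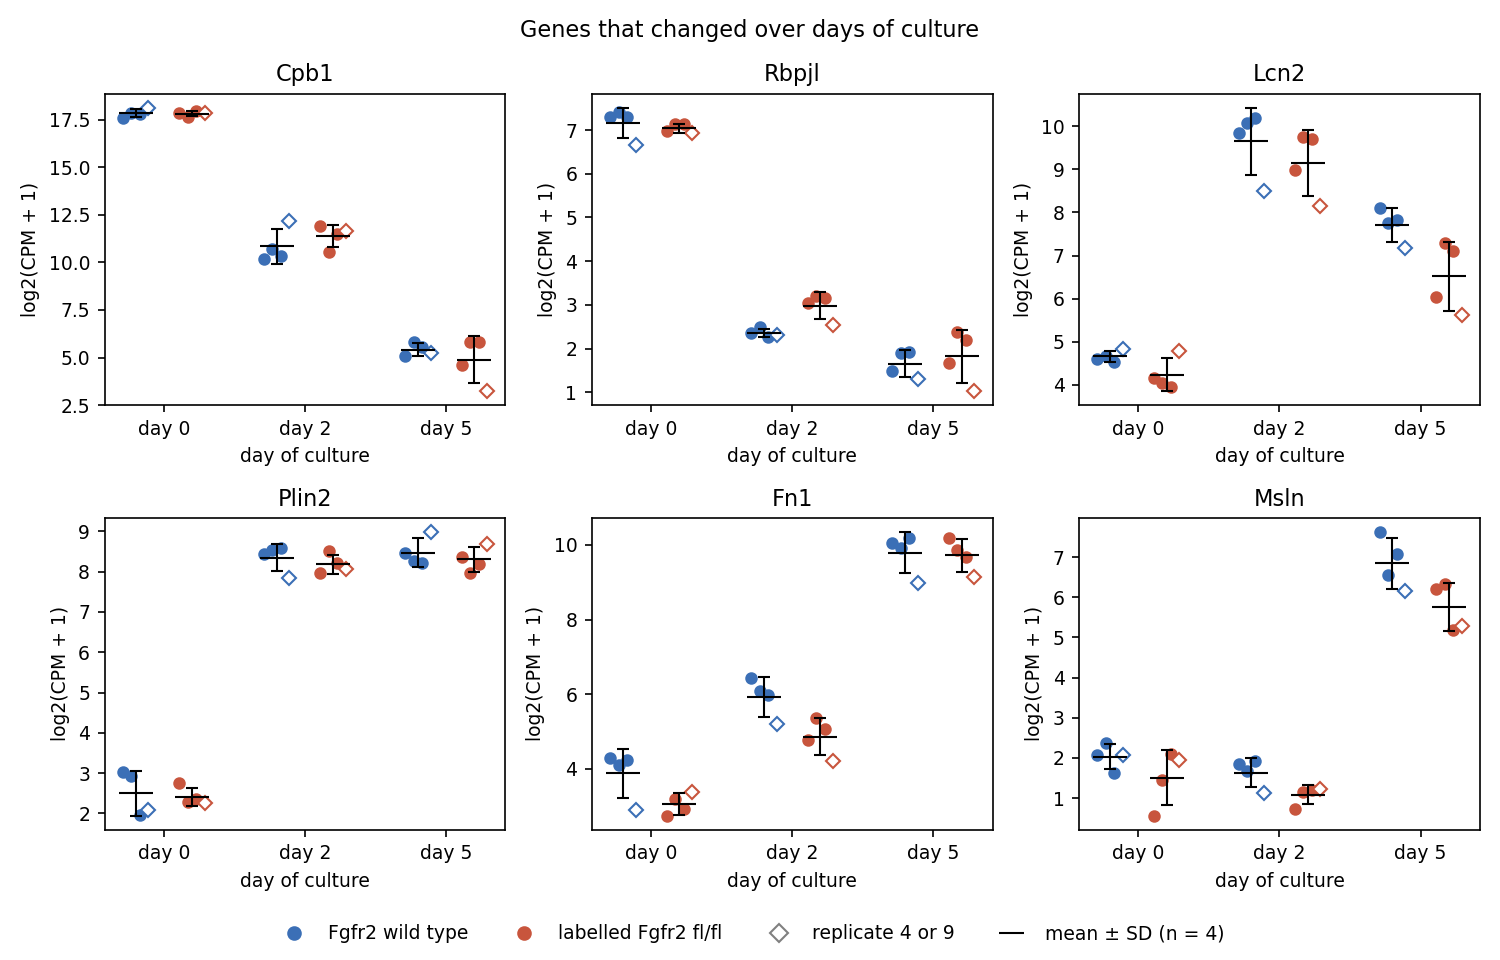
Level of Cpb1, Rbpjl, Lcn2, Plin2, Fn1 and Msln as log2(CPM + 1) on days 0, 2 and 5, normalised over all 24 libraries, 1 point per library (filled circles for the main code range, open diamonds for replicates 4 and 9) with the mean ± SD of 4 per genotype label in black. Cpb1 and Rbpjl fell and Lcn2 and Plin2 rose by day 2, and Fn1 and Msln rose between days 2 and 5, in both labels.

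From day 2 to day 5 acinar enzymes fell further in the wild-type explants, while single genes such as Msln, Muc5ac and Fn1 rose. The amylase gene Amy2a5 went from 23302 ± 19989 to 47.96 ± 34.99 CPM (SD, n = 4 each; log2 -8.92, SE 1.14, edgeR adjusted p = 3.29e-05). Mesothelin (Msln), a surface protein of many pancreatic tumours, rose from 2.19 ± 0.716 to 124 ± 55.8 CPM (log2 5.79, SE 0.33, edgeR adjusted p = 3.41e-08). The gastric mucin Muc5ac rose from 0.0874 ± 0.108 to 71.8 ± 41.7 CPM (8743 counts against 6 in all). Fibronectin (Fn1) rose from 63.2 ± 21.1 to 938 ± 299 CPM (log2 3.89, SE 0.33, edgeR adjusted p = 9.24e-07).

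In wild type 2993 genes were higher and 2792 lower on day 5 than on day 2, and 1456 and 826 of them changed over 2-fold. All 32 enzymes fell, with a median of -3.98, among them Pnlip at log2 -7.15, Cela1 at -6.34 and the granule membrane gene Gp2 at -6.28 (edgeR adjusted p = 7.04e-06, 2.47e-07 and 3.05e-06). Of 13 gastric metaplasia and PanIN markers 10 rose and 2 fell, including Anxa10 at log2 5.69 (SE 0.33, edgeR adjusted p = 3.41e-08; 2164 counts against 27). Of 29 cell cycle genes 26 rose, with Mcm4, of the replicative helicase, at 2.13, and of 22 YAP and TEAD targets 19 rose and 1 fell. Of 22 EMT and invasion genes 17 rose and 1 fell (19 and 1 adjusted over the list alone), and of 26 FGF and ERK feedback targets 18 rose and 2 fell (19 and 2 adjusted over the list alone), with the cyclin Ccnd1 at 4.81 (SE 0.30, edgeR adjusted p = 7.62e-08). The EGF receptor ligand Areg rose by 6.02, Igfbp3 by 4.68 and Ptgs2, a cyclooxygenase, by 4.20 on the log2 scale (edgeR adjusted p at most 2.09e-06). The tetraspanin Tspan8 rose by 3.77 and the keratin Krt7 of duct cells by 2.36. Where no second count is given, the count was the same adjusted over the list alone. The camera adjusted p was 1.6e-28 for the enzymes, 3.12e-05 for gastric markers, 2.25e-07 for the cell cycle, 9.18e-08 for YAP targets, 2.97e-07 for EMT and 1.14e-05 for FGF and ERK targets. None of these calls held with an estimated correlation (adjusted p = 0.239, 0.135, 0.315, 0.242, 0.242 and 0.242 with an estimated correlation).

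A further 7 lists were called by camera in wild type from day 2 to day 5, none of them with an estimated correlation. Of 22 NRF2 and glutathione genes 17 rose and 0 fell (18 and 0 adjusted over the list alone), with G6pdx, of the pentose phosphate path, at log2 1.76 (SE 0.14, edgeR adjusted p = 6.89e-07). Of 26 cholesterol and fatty acid genes 17 rose and 1 fell, also over the list alone, with Idi1 of isoprenoid synthesis at 1.81 (SE 0.15, edgeR adjusted p = 5.91e-07). Of 22 glycolysis and hypoxia genes 14 rose and 1 fell (17 and 1 adjusted over the list alone), with the pyruvate kinase Pkm at 1.48 (SE 0.14, edgeR adjusted p = 2.77e-06). Of 22 fibroblast and stellate markers 14 rose and 1 fell, also over the list alone, with Tagln at 2.97, while 0 of 15 endothelial markers rose and 5 fell. Of 22 integrin and laminin genes 13 rose and 1 fell (13 and 2 adjusted over the list alone). Of 25 immediate early and dissociation stress genes 2 rose and 13 fell, also over the list alone, with the heat shock gene Hspb1 at -2.92, but the list's median of -0.51 turned to 0.08 on log2(TPM + 1), where the median gene moved by 0.48. For these 7 lists in turn the camera adjusted p was 5.81e-07, 2.05e-06, 4.69e-05, 0.00185, 0.00192, 0.0082 and 0.00159 (adjusted p = 0.242, 0.239, 0.267, 0.483, 0.483, 0.426 and 0.242 with an estimated correlation). Fgfr2 rose (log2 1.87, SE 0.40, edgeR adjusted p = 0.00195). Without replicate 2 the genes passing fell to 1857 higher and 1652 lower, and without replicate 4 they were 3331 and 3282. On log2(TPM + 1) 5949 were higher and 685 lower.

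The libraries labelled fl/fl changed likewise from day 2 to day 5. Amy2a5 went from 31688 ± 16086 to 44.1 ± 12.4 CPM (SD, n = 4 each; log2 -9.49, SE 0.62, edgeR adjusted p = 6.24e-08). Msln rose from 1.12 ± 0.321 to 55.7 ± 22.8 CPM (log2 5.62, SE 0.33, edgeR adjusted p = 2.34e-08) and Fn1 from 28.8 ± 9.61 to 853 ± 245 CPM (log2 4.89, SE 0.28, edgeR adjusted p = 1.77e-08). Muc5ac stood at 0.0146 ± 0.0293 CPM on day 2 and 56.5 ± 38.4 CPM on day 5 (1 count against 7121). In all, 3638 genes were higher and 3605 lower on day 5, and 1899 and 1047 of them changed over 2-fold. All 32 enzymes fell, with a median of -4.63, among them Pnlip at log2 -8.34, Cela1 at -7.10 and Gp2 at -6.96 (edgeR adjusted p at most 1.37e-07). Areg rose from 9 to 3303 counts in all, Ptgs2 rose by log2 5.44, Ccnd1 by 4.85, Tspan8 by 4.53, the coagulation factor receptor F3 by 3.49 and Krt7 by 2.41 (edgeR adjusted p at most 2.68e-06).

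Of 11 gastric and PanIN markers 8 rose and 1 fell in fl/fl, of 29 cell cycle genes 22 rose and 1 fell, with Mcm2 at log2 1.46, and of 22 YAP and TEAD targets 19 rose and 2 fell. Of 21 EMT and invasion genes 18 rose (19 adjusted over the list alone), and of 26 FGF and ERK targets 19 rose and 2 fell (20 and 2 adjusted over the list alone). Of 22 fibroblast and stellate markers 20 rose and 0 fell, with the matrix protein Sparc at 2.77 and Tagln at 3.92, and of 22 integrin and laminin genes 14 rose and 2 fell. Of 22 glycolysis genes 18 rose and 2 fell, with Pkm at 1.48, of 26 cholesterol and fatty acid genes 16 rose and 3 fell, and of 21 NRF2 and glutathione genes 15 rose and 3 fell, with G6pdx at 1.72. Where 1 count is given, that adjusted over the list alone was the same. Camera adjusted p ran from 4.6e-27 for the enzymes to 0.00193 for the gastric and the cholesterol lists. None of these held with an estimated correlation, the nearest being the enzymes (adjusted p = 0.0586 with an estimated correlation), EMT, YAP and cholesterol lists (adjusted p = 0.0684 with an estimated correlation). For gastric markers, FGF targets, NRF2, glycolysis, integrins, fibroblast markers and the cell cycle the adjusted p was 0.167, 0.269, 0.269, 0.269, 0.269, 0.322 and 0.482 with an estimated correlation. Of 25 immediate early genes 2 rose and 16 fell (2 and 17 adjusted over the list alone; camera adjusted p = 0.00674, and adjusted p = 0.394 with an estimated correlation), with Hspb1 at -2.79, but the list's median of -0.78 turned to 0.09 on log2(TPM + 1). The islet and enteroendocrine gene Chga rose by 1.69 (edgeR adjusted p = 0.000349). Fgfr2 changed by log2 0.92 (SE 0.43, edgeR adjusted p = 0.0824), which did not pass. On log2(TPM + 1) 8179 genes were higher and 599 lower, with the median gene at 0.66, and without replicate 9 the edgeR counts were 3682 and 3730. In both labels 2498 genes rose and 2437 fell, of 13023, where independent calls would give 788 and 762, and 1 went opposite ways (r = 0.918 across genes).

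**Figure D3:**
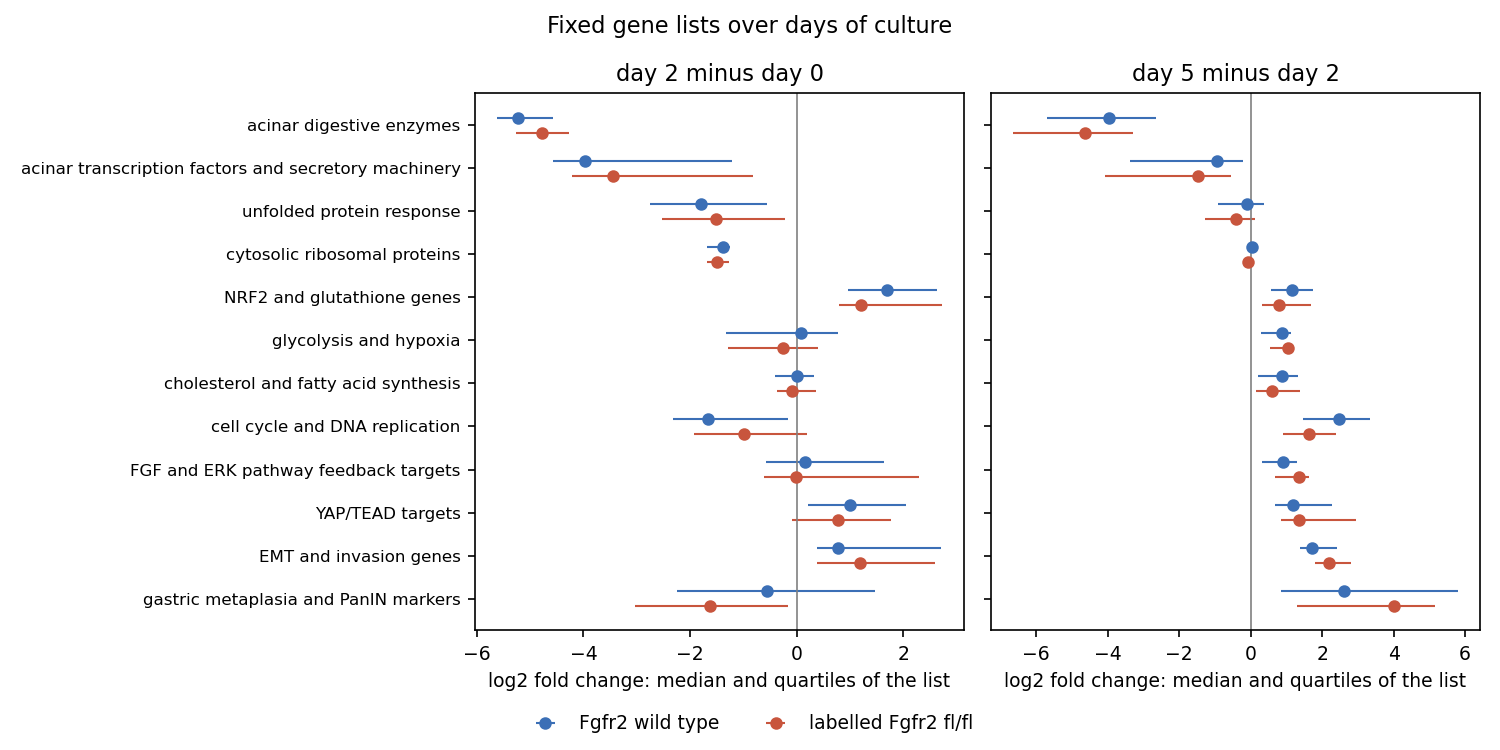
Median (point) and quartiles (bar) of the log2 fold change of 12 gene lists, for day 2 against day 0 and day 5 against day 2, by genotype label, on the TMM scale. Acinar enzymes fell at both steps, with medians of -5.23 and -3.98 in wild type and -4.77 and -4.63 in fl/fl, while the medians of the ribosomal and unfolded protein lists for day 2 turned positive on log2(TPM + 1).

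On day 0 the genes lower in the libraries labelled fl/fl included Reg3a and Reg3b, which encode secreted lectins, and pseudogene calls are given further below. Reg3a was 14.6 ± 11.2 CPM in the libraries labelled fl/fl and 201 ± 146 CPM in wild type (SD, n = 4 each; log2 -3.79, SE 0.52, edgeR adjusted p = 0.0035). Reg3b was 211 ± 76.1 and 880 ± 338 CPM (log2 -2.06, SE 0.26, edgeR adjusted p = 0.00151). The complement gene C4b was lower too, at 1.61 ± 1.99 against 18.8 ± 6.395 CPM (log2 -3.57, SE 0.45, edgeR adjusted p = 0.00151). The neuropeptide gene Gal was higher in fl/fl, at 40.8 ± 12.5 against 13.3 ± 6.50 CPM (log2 1.62, SE 0.30, edgeR adjusted p = 0.0337).

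In all, 6 genes were higher and 12 lower in fl/fl on day 0, of 8397 tested, and 632 had an unadjusted p under 0.05. Reg2 was 389 ± 476 against 4978 ± 2065 CPM (log2 -3.68, SE 0.68, edgeR adjusted p = 0.0337) and Reg3g 17.4 ± 10.1 against 74.5 ± 22.999 CPM (log2 -2.10, SE 0.32, edgeR adjusted p = 0.00871). With Reg3d (log2 -1.17, SE 0.22, edgeR adjusted p = 0.0337) these 5 genes lie together on chromosome 6, from 78347640 to 78445855 on GRCm39. Reg genes were noticed among the calls and not tested as a group, and Reg1, named after its values were seen, did not pass (log2 -1.10, SE 0.25, edgeR adjusted p = 0.112). Agr2 was lower by 1.96, the ion channel relative Tmc5 by 2.68, the adhesion gene Nfasc by 2.47 and the antiviral membrane gene Ifitm3 by 1.03, and the growth factor Pgf was higher by 1.05 and the semaphorin Sema7a by 0.65 on the log2 scale (edgeR adjusted p from 0.0103 to 0.0452). Leaving out any single replicate kept the calls of Reg3a, Reg3b and C4b. Without replicate 8 the count fell to 5, and Reg2, Reg3g, Reg3d, Agr2, Tmc5, Nfasc, Ifitm3, Gal, Pgf and Sema7a did not pass (adjusted p from 0.0581 to 0.227). Reg2 was also lost without replicate 2, 3, 6 or 7 (adjusted p at most 0.142), Ifitm3 without 6 (0.0582), Gal without 2 or 6 (0.108 and 0.0892), and Pgf without 1, 2 or 3 (0.136, 0.104 and 0.136). Reg3d was lost in 6, Tmc5 in 7 and Sema7a in 7 of the 8 leave-outs. The count was 11 without replicate 6, 34 without 9 and 37 without 4. The tests on log2(TPM + 1) passed 2 higher and 2 lower, and those on log2(TPM + 0.1) 2 higher and 0 lower, so every call of a lower gene was lost there.

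The 6 animals of the main code range gave 19 genes higher and 38 lower on day 0, and the term for code range gave 24 and 42. Within the main range code order and genotype cannot be told apart. In the fit with the term Reg2 was at log2 -4.34, Reg3a at -3.85, C4b at -3.62 and Gal at 1.62. Of 56 genes called in the 6 animals, 44 differed the same way between replicates 9 and 4, as did 54.2% of all genes, in a range of 1 animal per label with no test of its own. Among the gene lists, all 8 tested endothelial markers were lower in fl/fl (5 when adjusted over the list alone, 0 over all genes), such as Emcn at log2 -0.89 (adjusted p = 0.268) and Pecam1 at -0.69 (adjusted p = 0.445). Of 7 interferon response genes 6 were lower (1 adjusted over the list alone), with Ifih1 at -1.53 (adjusted p = 0.103), and all 9 fibroblast and all 10 cell cycle genes were lower, with 0 adjusted over the list alone. All 12 mitochondrial transcripts were higher (1 adjusted over the list alone), with mt-Co2 at 0.45 (adjusted p = 0.169). For these lists in turn the camera adjusted p was 3.3e-05, 0.000594, 0.0117, 0.00428 and 0.00062 (adjusted p = 0.416, 0.144, 0.563, 0.510 and 0.416 with an estimated correlation). The fibroblast call was lost without replicate 1, 2 or 9 (camera adjusted p = 0.192, 0.0551 and 0.132) and the cell cycle call without 9 (0.166). Of 25 lists 1 was higher and 7 lower, and 5 lists passed in all without replicate 1, 2 or 9.

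**Figure D4:**
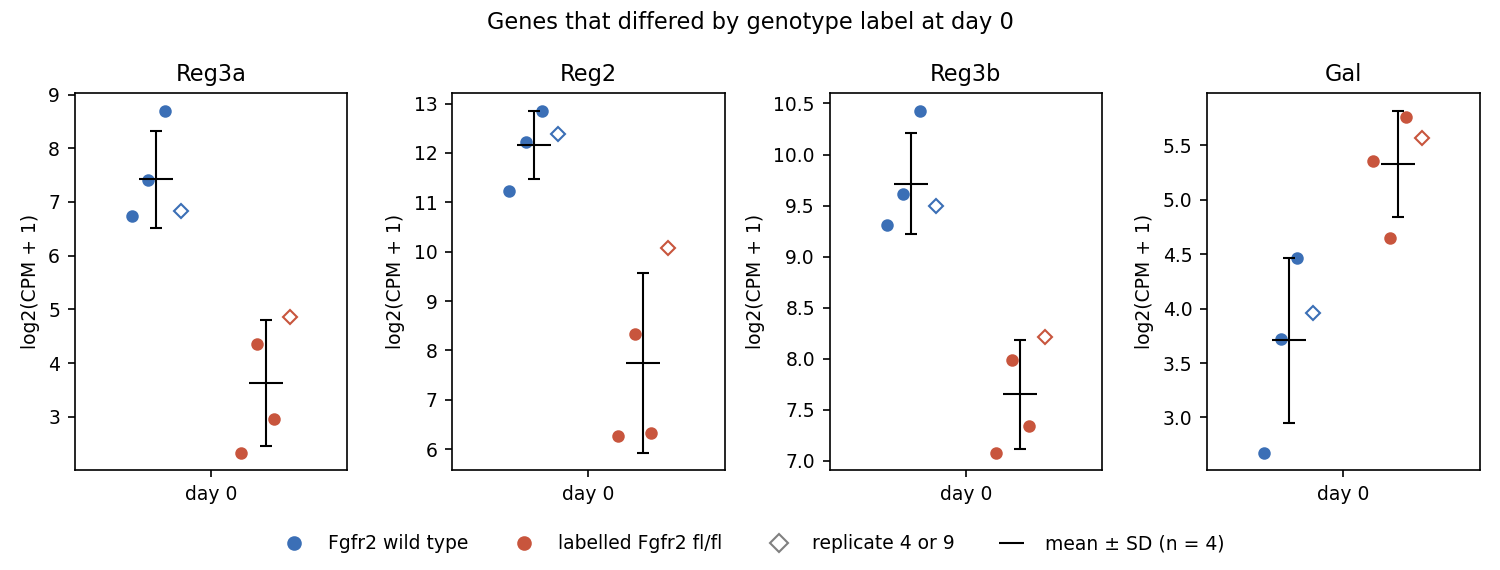
Level of Reg3a, Reg2, Reg3b and Gal on day 0 as log2(CPM + 1), normalised over the 8 day 0 libraries, 1 point per library with the mean and SD of 4 per genotype label. These 3 Reg genes were lower and Gal higher in the libraries labelled fl/fl; open diamonds are replicates 4 and 9.

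On day 2 the libraries labelled fl/fl stood on average higher in acinar genes and lower in glycolytic and duct genes. Single genes did not carry these differences past the threshold. The labels overlapped in the acinar share of counts, which was highest in wild-type replicate 4 (33.9%) and 20.2% in fl/fl replicate 7. Macrophage and leukocyte markers were lower in fl/fl as well, 10 of 11, with a median of -0.52 (1 adjusted over the list alone; camera adjusted p = 0.000255, and adjusted p = 0.279 with an estimated correlation). None of the list calls of day 2 held with an estimated correlation (adjusted p at least 0.279 with an estimated correlation). Cckar, the cholecystokinin receptor of acinar cells, was 53.5 ± 10.4 CPM in fl/fl and 20.8 ± 4.61 CPM in wild type (SD, n = 4 each; log2 1.36, SE 0.18, edgeR adjusted p = 0.0701). The hexokinase Hk1 was 23.2 ± 2.80 against 45.2 ± 11.1 CPM (log2 -0.97, SE 0.18, edgeR adjusted p = 0.161). Fn1 was 55.5 ± 18.5 against 119 ± 40.0 CPM (log2 -1.11, SE 0.30, edgeR adjusted p = 0.274). The edgeR test passed 2 genes, both higher in fl/fl, of 12365, and 1438 had an unadjusted p under 0.05.

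All 32 acinar enzymes were higher in fl/fl on day 2, with a median of 0.43 and Zg16 at log2 0.89, but 0 passed adjusted over the list alone. Of 22 acinar transcription factor and secretory genes 19 were higher (5 adjusted over the list alone), including Rbpjl at log2 0.77, Bhlha15, a regulator of secretory cell structure, at 1.18, and Ptf1a at 0.72. Of 24 unfolded protein response genes 23 were higher (2 adjusted over the list alone), with the kinase Eif2ak3 at 0.45. Of 22 glycolysis and hypoxia genes 20 were lower (9 adjusted over the list alone), with Ldha at -0.66, of 26 duct markers 22 were lower (3 adjusted over the list alone), with Tspan8 at -1.58, of 25 FGF and ERK targets 19 (0 adjusted over the list alone), and of 19 EMT and invasion genes 15 (3 adjusted over the list alone). Of 5 gastric and PanIN markers 4 were lower (4 adjusted over the list alone), such as Msln at -0.95 and Ctse at -0.97. None of these genes passed over all genes tested (edgeR adjusted p from 0.222 to 0.348). In turn the camera adjusted p of the 8 lists was 1.53e-06, 1.54e-05, 1.7e-06, 1.53e-06, 0.000255, 0.000702, 0.00177 and 0.0119 (adjusted p = 0.593, 0.279, 0.484, 0.484, 0.526, 0.593, 0.593 and 0.279 with an estimated correlation). The FGF and EMT calls were lost without replicate 9 (camera adjusted p = 0.0676 and 0.0586). Of 28 lists 4 were higher and 13 lower.

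The day 2 count rose with a term for the code range, but also on leaving out replicate 4 alone. Leaving out replicate 9 alone changed it little. The 6 animals of the main range gave 202 genes higher and 264 lower, and the term for code range gave 95 and 147. Neither separates genotype from code order, since the wild-type codes of the main range all come before the fl/fl codes. Of 456 genes called in the 6 animals, 349 differed the same way between replicates 9 and 4, the single pair of the other range, as did 56.1% of all genes. In the fit with the term Cckar (log2 1.36, edgeR adjusted p = 0.011), Bhlha15 (1.21, 0.028), Rbpjl (0.76, 0.033), Zg16 (0.97, 0.042) and the lipase relative Pnliprp1 (0.80, 0.04) were higher. So were Eif2ak3 (0.45, 0.034), the receptor Notch1 (0.64, 0.013) and the desaturase Scd1 (0.98, 0.034). Lower were Hk1 (-0.94, 0.0043), Fn1 (-1.09, 0.011), Ldha (-0.65, 0.022), Ptgs2 (-1.31, 0.027), Tspan8 (-1.56, 0.04) and the ERK phosphatase Dusp4 (-0.44, 0.044). C4b, named after its values were seen, was 7.61 ± 9.53 against 49.7 ± 17.9 CPM (SD, n = 4 each). Leaving out replicate 4 gave 225 higher and 277 lower, and leaving out 2, 7 or 9 gave 4 in all. DESeq2 gave 69 higher and 80 lower, and protein-coding genes alone gave 0, with 4 and 3 on log2(TPM + 1) and log2(TPM + 0.1). The acinar share of counts, which moves with these lists, was 27.1% against 21.6%.

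On day 5 fibroblast and islet markers stood higher and lipid synthesis, oxidative defence, glycolysis and cell cycle genes lower in the libraries labelled fl/fl, again without passing gene by gene. These list calls were lost with an estimated correlation (adjusted p at least 0.402 with an estimated correlation). The matrix proteoglycan Lum was 15.7 ± 7.57 CPM in fl/fl and 4.35 ± 0.732 CPM in wild type (SD, n = 4 each; log2 1.84, SE 0.37, edgeR adjusted p = 0.273). Cyp51, of cholesterol synthesis, was 51.9 ± 3.72 against 71.8 ± 1.80 CPM (log2 -0.47, SE 0.08, edgeR adjusted p = 0.273). The edgeR test passed 4 genes, all higher in fl/fl, of 13741, and 1603 had an unadjusted p under 0.05.

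All 22 fibroblast and stellate markers were higher in fl/fl on day 5, with a median of 0.99 (14 adjusted over the list alone), among them Col6a1 at log2 1.71 and Dpt at 2.20. Elastin (Eln), of the matrix, was at 3.07. Of 16 islet markers 15 were higher (3 adjusted over the list alone), with Ins2 at 1.34 and Iapp at 1.02. Of 26 cholesterol and fatty acid genes 24 were lower (14 lower and 1 higher adjusted over the list alone), with Idi1 at -0.86 and Fdps at -0.63. Of 22 NRF2 and glutathione genes 21 were lower (7 adjusted over the list alone), with Gsta1 at -1.30, and of 22 glycolysis genes 19 were lower (10 adjusted over the list alone), with Pkm at -0.43 and Eno1 at -0.50. All 30 cell cycle genes were lower, with a median of -0.88 (0 adjusted over the list alone) and Mcm6 at -0.41. Fgf2 was at 1.01, Fgfbp1, a carrier of fibroblast growth factors, at -1.05, Anxa10 at -0.98 and C4b at -2.13. None of these genes passed over all genes tested (edgeR adjusted p from 0.242 to 0.332). The camera adjusted p was 9.48e-10 for fibroblast, 5.06e-07 for islet, 6.2e-11 for cholesterol, 7.23e-08 for NRF2, 5.49e-07 for glycolysis and 3.97e-07 for cell cycle genes (adjusted p = 0.402 with an estimated correlation, and 0.588 for the cell cycle). Of 30 lists 5 were higher and 9 lower, and without replicate 9 the number passing was 9. The 6 animals of the main range passed 3 genes, all higher, and the term for code range 4 higher and 1 lower. These 3 were also higher in replicate 9 than in 4, as a single pair. Without replicate 7 the counts were 191 higher and 23 lower, without 1, 3 or 8 they were 2 in all, DESeq2 gave 118 and 59, and protein-coding genes alone gave 0.

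Without a term for code range, the calls that recurred between days were processed pseudogenes of ribosomal protein genes. Rps15a-ps7 and Rps15a-ps8 on day 0, and Gm10167, the other call of day 5, fell outside the rule for named genes and were chosen after their values were seen. Rps13-ps1 was 29.0 ± 5.51 CPM in the libraries labelled fl/fl and 0.138 ± 0.275 CPM in wild type on day 0 (SD, n = 4 each; log2 7.73, SE 0.39, edgeR adjusted p = 1.59e-08; 1292 counts against 6). It had 3827 counts against 13 on day 2 (log2 8.31, SE 0.51, edgeR adjusted p = 0.000161) and 5280 against 53 on day 5 (log2 6.67, SE 0.33, edgeR adjusted p = 3.15e-05). Rps15a-ps8 had 197 counts against 0, 754 against 1 and 1144 against 1 on days 0, 2 and 5. Rps15a-ps7 was higher on day 0 (log2 3.25, edgeR adjusted p = 0.00871; adjusted p = 0.0581 without replicate 8) and on day 5 (2.46, 0.0395). The day 5 call was lost without replicate 1, 2, 3, 8 or 9 (adjusted p = 0.196, 0.219, 0.231, 0.193 and 0.112) and among the 6 animals (0.0739). The parent gene Rps13 was lower on day 2 (log2 -0.70, SE 0.10, edgeR adjusted p = 0.094), which did not pass. With the term for code range Rps13 passed on day 0 (log2 -0.60, edgeR adjusted p = 0.0335) and day 2 (log2 -0.70, edgeR adjusted p = 0.013). Counts of such copies are uncertain, since they share most of their sequence with the parent. Days 0 and 2 shared 2 calls, days 2 and 5 shared 2, and days 0 and 5 shared 3, where independent calls would give 0.00144, 0.000656 and 0.0018. With the term for code range the shared calls were 14, 5 and 4, and not all were pseudogenes: days 0 and 2 shared Pgf, Kitl, Itih4, Fads2, Ifitm3, Tmc5, Fnip2, Ldha and Rps13, and all 3 days shared C4b. The days hold the same animals, so these overlaps are not independent.

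**Figure D5:**
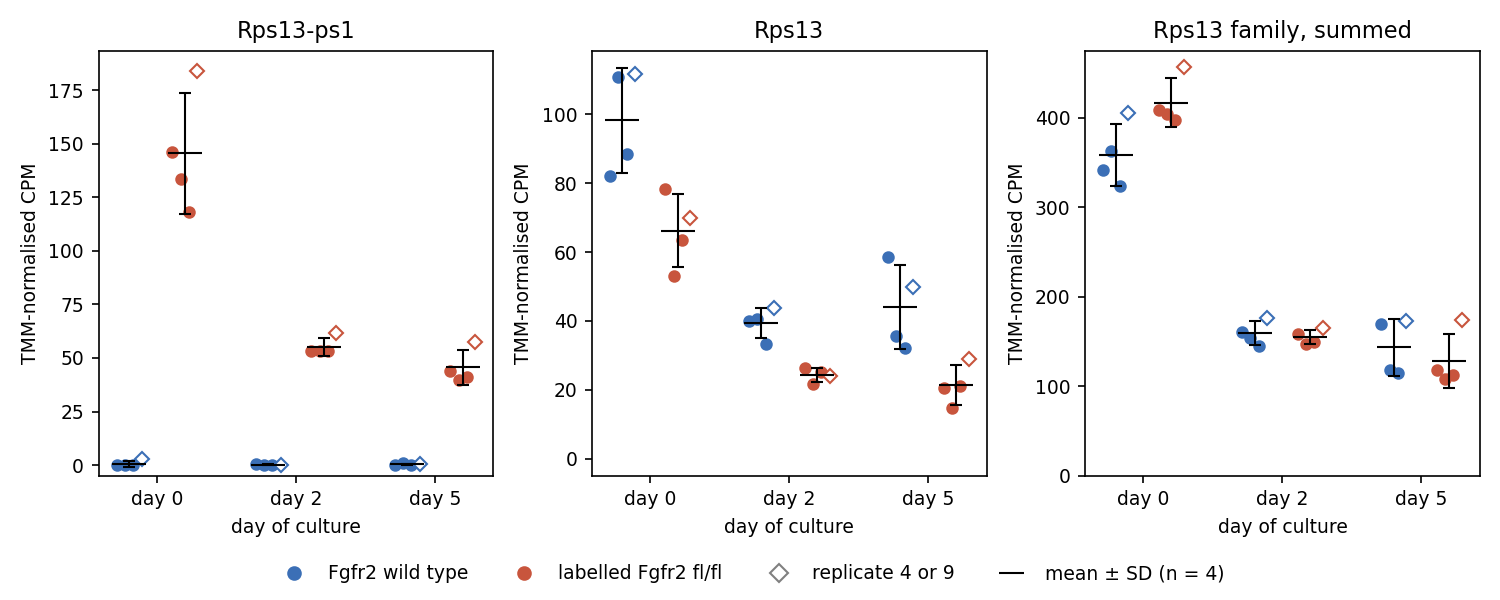
CPM, normalised over all 24 libraries, of Rps13-ps1, its parent Rps13 and the sum of the Rps13 family by day and genotype label, 1 point per library with the mean and SD of 4. Rps13-ps1 was 145.5 ± 28.2 CPM on day 0 in the libraries labelled fl/fl and 0.690 ± 1.38 CPM in wild type, and Rps13 was 66.1 ± 10.6 and 98.2 ± 15.3 CPM.

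Whether the labels changed differently over days was tested directly, and no gene passed. From day 0 to day 2 edgeR passed 0 of 14095 genes (901 with an unadjusted p under 0.05, lowest adjusted p = 0.510), DESeq2 passed 3, and limma 1 and 2 on log2(TPM + 1) and log2(TPM + 0.1). From day 2 to day 5 edgeR passed 0 (824 with an unadjusted p under 0.05, lowest adjusted p = 0.806), DESeq2 2, and limma 1 on each scale. Fgfr2 differed by log2 -0.92 (SE 0.75, edgeR adjusted p = 0.902) and -0.93 (SE 0.62, edgeR adjusted p = 0.901), the former turning to 0.05 on log2(TPM + 1). Tnip1, an inhibitor of NF-kappaB, was at 0.98 for days 0 to 2 (SE 0.20, edgeR adjusted p = 0.510), and Ggct, of glutathione turnover, at 1.18 for days 2 to 5 (SE 0.29, edgeR adjusted p = 0.806). For days 0 to 2 the edgeR count was 5 without replicate 9, 2 without replicate 4 and 10 among the 6 animals of the main range. By list, the fall of acinar enzymes was smaller in fl/fl up to day 2 (median difference 0.36, camera adjusted p = 0.0112) and larger after it (-0.68, camera adjusted p = 1.68e-12), with 0 members past the threshold over the list alone. These calls were lost with an estimated correlation (adjusted p = 0.922 and 0.215 with an estimated correlation). The former was also lost without replicate 1, 3 or 6 (camera adjusted p = 0.0527, 0.132 and 0.0769). With the animal as a block, 8 lists passed for days 0 to 2 in place of 4.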

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

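The tests of shared reads, pseudogene transcription, linked variants, acinar loss, swapped labels and the IIIb exon were chosen only after the results they bear on were seen, as were the counts of splits that use the code range. The other counts of splits and the test of depth were set before.

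Rps13-ps1, a processed pseudogene of a ribosomal protein gene, had 1292, 3827 and 5280 counts in the libraries labelled fl/fl and 6, 13 and 53 in wild type on days 0, 2 and 5. Transcription of the pseudogene alone would raise the sum of Rps13 and its pseudogenes by the same amount, and on day 2 that sum fell short of the gain by 8.286 standard errors, which argues against it as the whole cause. Reads moved from Rps13 and its other copies may account for much of it, since the sum changed by 40.6%, -7.22% and -34.5% of the gain on the 3 days and Rps13 was lower in 16 of 16 pairs of libraries on each day. Variants in the chromosome segment carried with the fl/fl allele stay open. Unadjusted p under 0.01 was more frequent within 20 Mb of Fgfr2 on day 2 (7.61% against 3.21% of genes, one-sided Fisher's exact p = 0.000462, adjusted over 3 days 0.00139), but not on day 5 (p = 0.5113) and at p = 0.0504 on day 0. That frequency concerns protein-coding genes near Fgfr2 and not the division of reads among copies. It cannot decide whether such variants moved reads to the pseudogenes, and the positions of the parent genes were not examined. The genotype label, the only biological difference in the design, is confounded with any such segment.

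The Fgfr2 count was not lower in the libraries labelled fl/fl. A swap of labels between animals stays open. Rps13-ps1 was higher in the library labelled fl/fl in 144 of 144 pairs, but it was singled out because it separates the labels, and an exchange of every label would look the same. Counts from transcripts that lack the exons removed in fl/fl may remain, and on day 5 the IIIb share was lower in fl/fl without passing (exact permutation p = 0.1714, n = 4 each). The IIIb exon is typical of epithelial cells, and on day 5 the 22 fibroblast markers had a median log2 difference of 0.99 in fl/fl. The IIIb share therefore does not separate the loss of exons from the mix of cells. A transcript with neither the IIIb nor the IIIc exon, singled out after its values were seen, made up 51.1% ± 29.8 of Fgfr2 in fl/fl and 16.1% ± 10.99 in wild type on day 0, higher in 15 of 16 pairs (SD, n = 4 each; exact p = 0.0571, adjusted over 3 days 0.171), with 55.57 summed counts against 8.9. The exact p was 0.0286 without replicate 8 and 0.0571 to 0.2 on leaving out any other animal. Among the 6 animals of the main code range it was 0.1, the smallest possible. On days 2 and 5 this transcript made up 31.0% against 16.1% and 36.3% against 23.6% (exact p = 0.2 and 0.314). Whether it lacks the exons removed in fl/fl is not given. That this cannot be told apart from no change rests on 0 to 58.9 expected counts of IIIb transcripts per library. A partial loss of the gene, as Cre acts in a share of the cells, was not tested.

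The day 2 libraries were ordered along their first principal component other than by genotype, with replicates 4, 6 and 9 on 1 side. Over the 8 libraries this component, computed without acinar enzymes, followed the acinar share of counts (Pearson r = 0.9007, permutation p = 0.00384, adjusted over 2 relations 0.00769; Spearman rho = 0.857, p = 0.0107). Without the 2 libraries farthest from the median share r was 0.882 (permutation p = 0.0222), so unequal loss of acinar transcripts between animals may underlie the order. Only the enzyme list was removed, so other acinar genes could still shape the component, and the relation is not an independent check. Depth gave r = -0.3608 (permutation p = 0.376), which leaves it open. No biological explanation from the design was tested, since each label lies on both sides.

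Other splits of the 8 libraries of a comparison were counted among 35, the real one included. On day 0, 1 split of the 35 gave as many genes as the real 18 (highest other 4). That share is under 0.05 for this day by itself. It is not adjusted over the days tested and leaves the code range aside, so chance is not excluded. On day 2 and on day 5, 3 splits gave as many as the real 2 and 4, so chance is not excluded there either. The highest others, 2778 and 354 genes, set wild-type replicates 1, 2 and 3 with fl/fl replicate 7 against replicates 4, 6, 8 and 9, which points to a structure of the samples other than the label. Of the 20 splits that set replicates 4 and 9 apart, as the labels do, 1 gave as many on each day (highest other 1, 0 and 0), and 20 are too few for a share under 0.05. With the term for code range 1 of 20 splits gave as many genes on each day (66, 242 and 5 real; 1, 0 and 0 highest other), again too few. For days within a label 1 of 35 gave as many in each of the 4 comparisons (7220, 5785, 7095 and 7243 real; 1, 1, 0 and 1 highest other). Of the splits that part every animal's pair, 1 of 8 did (0, 1, 0 and 0 highest other), and 8 are too few. For the difference between labels over days 35 of 35 gave as many as the real 0, with highest others of 181 and 752.

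Among 35 splits chance is not excluded for any count of lists. On days 0, 2 and 5, 6, 4 and 6 of 35 splits passed as many lists (8, 17 and 14 real; 11, 19 and 17 highest other). With the term for code range 2, 1 and 4 of 20 did (10, 17 and 16 real; 10, 11 and 19 highest other), and 20 splits are too few for a share under 0.05. For day 2 against 0 and day 5 against 2, 19 and 13 of 35 did in wild type (7 and 17 real; 12 and 20 highest other), and 8 and 9 in fl/fl (8 and 15 real; 11 and 18 highest other). For the difference between labels 8 and 5 of 35 did (4 and 16 real; 9 and 19 highest other). Overlaps of genotype calls were reached by 2 of 35 splits for days 0 and 2 (2 real, 4 highest other), 3 for days 2 and 5 (2 real, 47 highest other) and 2 for days 0 and 5 (3 real, 4 highest other).

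Single libraries lay apart from their group in 18 of 118 groups of 4 screened by Dixon's ratio. Its chance rate of about 1 in 20 is for normal values and does not apply where the other libraries were all at 0. There any single value above 0 gives a ratio of 1, as for the IIIc percentages, wild-type Rps13-ps1 and Muc5ac. Rps13-ps1 on day 0 was also screened on both scales, so the 18 do not measure an excess of outlying libraries. The percent of Fgfr2 transcripts with the IIIb exon was 49.69 in replicate 7 on day 0 (0 in the other fl/fl libraries) and 9.02 in replicate 8 on day 2 (0 to 0.94). That with the IIIc exon was 17.43 in replicate 2 on day 0, 19.78 in replicate 4 on day 2, 7.27 in replicate 9 on day 2 and 15.09 in replicate 4 on day 5 (0 in the others of each group). An Fgfr2 transcript without either exon was at 0% in replicate 4 on day 5 (29.63 to 32.52 in the others). The position of replicate 4 on day 2 along the line from day 0 to day 5 was 52.92% (69.53 to 72.34). Rps13-ps1, normalised over 24 libraries, was 2.761 CPM in replicate 4 on day 0 and 0.5581 CPM in replicate 1 on day 2 (0 in the other wild-type libraries), and 61.64 CPM in replicate 9 on day 2 (53.05 to 53.35). Over the 8 day 0 libraries replicate 4 had 0.5508 CPM.

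On day 2 Cckar was 27.75 CPM in replicate 2 (18.3 to 18.84 in the other wild-type libraries), Cpb1 was 4621 CPM in replicate 4 (1153 to 1693) and Tff2 was 148.9 CPM in replicate 4 (51.55 to 66.54). Plin2 was 5.73 CPM in replicate 6 on day 0 (3.775 to 4.103). On day 2 replicate 6 had 0.0585 CPM of Muc5ac (0 in the other fl/fl libraries) and 0.6435 CPM of Msln (1.222 to 1.321).

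Lists whose change over days differed between labels by camera are given as the median of the differences in log2 change, fl/fl minus wild type. From day 0 to day 2 these were 0.359 for acinar enzymes, 0.3218 for acinar transcription factors, 0.2491 for the unfolded protein response and -0.293 for glycolysis (camera adjusted p from 0.00512 to 0.0112; adjusted p = 0.922 with an estimated correlation). Without replicate 3 only 1 list passed, and the enzyme, transcription factor and unfolded protein calls were lost (camera adjusted p = 0.132, 0.0936 and 0.0865). Without replicates 4 or 9 the number was 7 and 8. From day 2 to day 5 they were -0.6831 for acinar enzymes, -0.4108 for acinar transcription factors, -0.7186 for the cell cycle, -0.2062 for the unfolded protein response, -0.303 for NRF2 genes, -0.09027 for cholesterol synthesis (0.0778 on log2(TPM + 1)) and -0.282 for mitochondrial transcripts. Higher were fibroblast markers (0.9206), endothelial markers (0.9403), islet markers (0.8742), tuft markers (0.8768), EMT genes (0.5528), interferon response (0.3834), YAP targets (0.3409), FGF and ERK targets (0.2421) and integrins (0.1947). The camera adjusted p of these 16 ran from 1.68e-12 to 0.0414, and none held with an estimated correlation (adjusted p at least 0.215 with an estimated correlation).

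Of these, the mitochondrial, interferon, tuft, YAP and FGF calls were lost without replicate 9 (camera adjusted p = 0.412, 0.0717, 0.0752, 0.115 and 0.0657), and the tuft, YAP and FGF calls without replicate 6 (0.0502, 0.0502 and 0.173). The integrin call was lost without replicate 1 (0.109), and the FGF call without 1, 2, 3 or 8 (0.150, 0.105, 0.0810 and 0.0555).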

How the results depend on the processing

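The term for code range, the 6 animals of the main range and the share of expected counts were chosen after seeing the data. Of 153 alternative counts of genes 109 stayed within 1.5 times the value reported. Of 804 alternatives for named lists 693 kept the call, 111 lost it and 0 turned camera's direction relative to other genes. These were RLE factors, left-out animals, the animal or code range term, the 6 animals and an estimated correlation, for which direction was not compared. Camera was not run with the other alternatives, the TPM scales and DESeq2 among them, so its direction there was not tested. Medians did turn sign on both TPM scales: those of the ribosomal, mitochondrial and unfolded protein lists up to day 2 and of immediate early genes after it in both labels, and that of cholesterol synthesis for the difference after day 2. Of 2418 for named genes 2207 kept their call and direction, 86 lost a call, 110 gained one and 15 turned direction. DESeq2 gave no adjusted p for 3 named genes. At 8725990 to 13159985 counts per library, Fgfr2 with 23 counts in wild type on day 0 was too low for edgeR. The cause of the changes below was not tested, except that TPM carries no correction for the loss of enzymes and that fewer genes or animals enter some fits.

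For genotype on day 0 (18 genes) no filter gave 154, the TPM tests 4 and 2, the term for code range 66 and the 6 animals 57, with 5 to 37 on leaving out an animal. On day 2 (2 genes) no filter gave 22, DESeq2 149, the TPM + 1 test 4, protein-coding genes 0, a single fit of 24 libraries 20, the term 242 and the 6 animals 466, with 2 to 502 on leaving out an animal. On day 5 (4 genes) no filter gave 16, DESeq2 177, protein-coding genes 0 and the single fit 23, with 2 to 214 on leaving out an animal.

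For day 2 against day 0 the TPM + 1 and TPM + 0.1 tests gave 11719 and 11813 genes in wild type (5729 to 7403 on leaving out an animal) and 11683 and 11848 in fl/fl (5870 to 6916). For day 5 against day 2 leaving out an animal gave 3509 to 6613 in wild type and 5383 to 7412 in fl/fl. With the animal as a block (replicate block) the counts were 3980 higher and 3384 lower, 3322 and 3130, 3927 and 3284, and 3835 and 3807 for the 4 comparisons of days. For the difference between labels up to day 2 (0 genes) no filter gave 8, DESeq2 3, the TPM tests 1 and 2 and the 6 animals 10, with 0 to 5 on leaving out an animal. After day 2 (0 genes) they gave 31, 2, 1 and 1, with 0 on leaving out any animal. The block gave 0 for both.

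With an estimated correlation 0 lists passed in each of the 9 comparisons. Leaving out an animal gave 5 to 11, 12 to 18 and 9 to 15 lists on days 0, 2 and 5, 6 to 10 and 17 to 19 for days in wild type, 7 to 9 and 13 to 16 in fl/fl, and 1 to 8 and 13 to 18 for the differences. For the difference up to day 2 the replicate block and the 6 animals gave 8 and 7 lists in place of 4, and the block moved no other count of genes or lists by over 1.5 times. Shared calls with the term for code range were 14 for days 0 and 2 and 5 for days 2 and 5.

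The day 5 log2 difference of Fgfr2, -0.02, turned to 0.13 and 0.155 in the TPM + 1 and TPM + 0.1 tests, 0.046 with the term and up to 0.18 on leaving out an animal (range -0.32 to 0.18). Its change from day 0 to day 2 turned to 0.66 and 1.13 in wild type, to 0.71 and 1.18 in fl/fl and to 0.0457 and 0.0584 for their difference, and Pdia6 in fl/fl turned to 0.254 and 0.258. The IIIb difference on day 5 was -29.9 points without replicate 4, with a range of -29.9 to -14.2. Leaving out an animal gave 0 to 16.6 points on day 0 and -10.7 to -2.60 on day 2. The acinar difference on day 5 was 0.114 points in the 6 animals and -0.820 to -0.082 on leaving out an animal, and 0.609 to 1.79 and 3.42 to 9.59 on days 0 and 2.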

Other observations

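Of 20 p53 targets, a list not described above, 12 rose and 5 fell by day 2 in wild type and 13 and 5 in the libraries labelled fl/fl, with the same counts adjusted over the list alone. The list did not pass by camera (adjusted p = 0.0684 and 0.101). It passed by fry (adjusted p = 6.23e-07 and 1.3e-05), which in the simulated wild-type design also called 4 of 30 unchanged lists. From day 2 to day 5, 6 of 13 mitochondrially encoded transcripts were higher in wild type (7 adjusted over the list alone; camera adjusted p = 0.000116, and adjusted p = 0.242 with an estimated correlation) and 4 in fl/fl (4 adjusted over the list alone; camera adjusted p = 0.036, and adjusted p = 0.482 with an estimated correlation). In wild type 11 of 18 genes of the EGF receptor family and its ligands rose and 4 fell from day 2 to day 5 (12 and 4 adjusted over the list alone; camera adjusted p = 0.0203, and adjusted p = 0.242 with an estimated correlation), while 1 of 12 genes of antigen presentation rose and 6 fell (1 and 7 adjusted over the list alone; camera adjusted p = 0.0139, and adjusted p = 0.257 with an estimated correlation). In fl/fl 5 of 24 unfolded protein response genes rose and 11 fell over the same days (6 and 11 adjusted over the list alone; camera adjusted p = 0.0373, and adjusted p = 0.482 with an estimated correlation).

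Between labels, on day 5 all 5 tuft and enteroendocrine markers were higher, with a median of 0.89 (2 adjusted over the list alone; camera adjusted p = 0.0133, and adjusted p = 0.402 with an estimated correlation), as were 14 of 15 endothelial markers, with a median of 0.71 (0 adjusted over the list alone; camera adjusted p = 0.0167, and adjusted p = 0.699 with an estimated correlation). The most abundant 10 genes took 61.8% of counts in wild type and 63.7% in fl/fl on day 0, and 11.4% and 11.2% on day 5.

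A hypothesis is that the fl/fl explants changed more slowly in culture, set before its test was run. Each day 2 library was placed on the line from the day 0 mean (0%) to the day 5 mean (100%) over all genes. The fl/fl libraries stood at 59.5% ± 5.1 and wild type at 66.4% ± 9.1 (SD, n = 4 each), fl/fl being lower in 12 of 16 pairs, which did not pass (exact permutation p = 0.2571). Among the 6 animals of the main code range the positions were 61.7% ± 3.35 and 71.0% ± 1.41, lower in 9 of 9 pairs (n = 3 each; exact p = 0.1, the smallest possible). Such a delay may exist, and these samples do not decide it.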
